A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

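RNA-seq was carried out on small-intestinal crypts of 2-month-old C57BL/6 mice with the Apc Min mutation. The labels give 2 groups of 2 libraries, Apc Min and Apc Min with Zmynd8 deleted in the intestinal epithelium. The series' design text says that each library mixed equal masses of RNA from 3 mice. Neither source says whether the pools of a group differ in litter or day, so p-values measure the spread between these pools. The labels' protocols name an NEBNext Ultra RNA kit and paired-end sequencing on a HiSeq3000. The submitters' processing notes name HISAT2, BWA and SICER and the builds mm10 and hg38, without roles or versions. The counting tool, the annotation and any use of strand are not given in the sources used here. A further 4 ChIP-seq libraries from HCT116 cells were not analysed here.

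The authors deposited a table with 1 expression value per gene and library, a mean per group, a log2 fold change, a p-value and a q-value, per the file headers. The file headers name no unit for the expression values. The deposited values were read as FPKM (reads scaled by gene length and by the library's total), because each is a whole number of reads divided by a gene length and by 1 total per library. The authors' group means equalled the mean of the 2 libraries within 1e-06 for 12982 genes in Apc Min and 12579 in the other group, and were set to 0 where that mean was under 1 (376 and 780 genes). The 1 gene left over in Apc Min differed by rounding of the last digit. The authors' log2 fold change was the log2 of the ratio of the means for all 13359 genes, within 0.001. The test behind the deposited p-values and q-values is not given in the sources used here. Of 13527 entries in the table, 168 repeated another entry exactly, all of them with a deposited q-value under 0.05, and each was used once. All 13359 distinct genes had a mean of at least 1 FPKM in 1 or both groups, so genes below that level in both groups were not analysed here. Coordinates are those of the table, where mm10 is the mouse build in the processing notes. The number of unused per-sample columns was 0.

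Whole reads were recovered by finding, for each gene, the length that turned its 4 FPKM values into whole numbers within 0.002 reads. This worked for 13359 of 13359 genes. The library totals behind the values, taken from 195 to 203 short genes per library, were 44718091 and 48778712 reads for Apc Min replicates 1 and 2, and 46551218 and 47990019 for the libraries labelled knockout. Tested on simulated data, the recovery returned 98.2% of 600 genes exactly. What share of the spread between the 2 libraries of a group is counting error was not tested by expression level.

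The comparison was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend and robust moderation of the variances (eBayes). Genes with at least 1 FPKM in at least 2 libraries were tested, which left 12948. The model had genotype as its only term. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and intervals are at 95%. The residual degrees of freedom were 2, and the median prior degrees of freedom were 3.02. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, over 40 lists with at least 3 measured members. The same lists were tested with camera at an estimated correlation and with fry. With 2 residual degrees of freedom a correlation is poorly estimated, so missing the threshold with it does not show that a list is unchanged. Passing at the preset value alone does not settle that it changed. The lists hold pathways, intestinal cell types, other cell types and technical markers, written from textbook knowledge. The tests, lists and alternatives were fixed before the data were examined. The fixed design named a count test for raw counts and this limma test for normalized values; the unit found here called for the latter.

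Genes named in the text follow a rule fixed with the design. They are Zmynd8, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold, with the same direction in every pairing of libraries and a mean of at least 1 FPKM in the higher group. Predicted genes and immunoglobulin or T cell receptor segments were counted and not named. Members of the cholesterol synthesis list could be named, with up to 4 members of smallest p from each other list, and Srebf2, Insig1, Ccn1, Ccn2, Ankrd1, Lgr5 and Axin2. Some genes that the rule covers are not reported here. Because any use of strand is not given, values of Abcg5, Ccnd1, Cdc20, Ccna2, Fgf15, Gata6 and Dbp, which overlap a gene on the opposite strand, are uncertain. Genes named outside this rule are said to be chosen after their values were seen.

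Tested on simulated data with 12915 genes and the spread of these libraries, the limma test recovered 90.1% of 71 genes changed 4-fold, 10.4% of 67 changed 2-fold and 0% of 62 changed 1.5-fold. In that simulation 5 calls, 6.58% of all, were unchanged genes. Its changed genes were drawn from well-covered ones, its genes varied independently, and both groups had the same spread. The SD of the real log2 difference was 0.43 between the control libraries and 0.30 between those labelled knockout. These rates therefore need not hold for the real libraries. The alternatives were limma without the trend, quantile normalization, median-ratio scaling, no filter on low values, a filter at a mean of 5 FPKM, a pseudocount of 0.1, an added log2 fold change of at least 1, the replicate number as a block, and each library left out in turn, which applied the filter on low values anew and so dropped some list members. A fit without 1 library keeps 1 library in that group, so its spread comes from the other group alone and its p-values decide little. A limma voom fit on the recovered reads was added after the data had been seen. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.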

Results

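RNA-seq measured gene expression in crypts of the small intestine from 2-month-old mice with the Apc Min mutation, which truncates the Wnt pathway regulator Apc and leads to intestinal adenomas. There were 2 libraries of Apc Min mice, used as controls, and 2 of Apc Min mice labelled as lacking Zmynd8 in the intestinal epithelium. ZMYND8 is a chromatin protein that reads histone marks. The series' title ties it to the mevalonate pathway and to YAP, so the comparison asked how cholesterol synthesis genes, YAP targets and the rest of the crypt transcriptome differed between these groups. Each library pooled 3 mice. The control libraries held 43457250 and 47500045 reads on the 13359 listed genes, and the libraries labelled knockout 45304190 and 46779799. Across genes, which are not independent replicates, Pearson's r was 0.971 between the control libraries and 0.986 between those labelled knockout. Between the groups it ran from 0.9502 to 0.969, the highest being control replicate 2 with replicate 1 of the libraries labelled knockout. The first principal component, with 62.1% of the variance, separated the groups, and the second, with 26.1%, separated control replicate 1 from control replicate 2. A further 4 ChIP-seq libraries of HCT116, a human colorectal cancer cell line, were not analysed here.

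Zmynd8 RNA was not lower in the libraries labelled knockout. The gene (protein coding, chromosome 2, 165784152 to 165898981, minus strand) stood at 6.94 and 4.73 FPKM in the controls and at 7.30 and 7.65 FPKM in the libraries labelled knockout. Its log2 fold change was 0.33 (SE 0.18, 95% interval -0.13 to 0.79, limma adjusted p = 0.293). These are gene-level values that do not show single exons, and the labels do not say which part of the gene was deleted. The targeted gene therefore gave no check of the labels, and every direction below rests on the labels alone.

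Cyp3a11, a cytochrome P450 of drug and steroid metabolism, rose from 24.99 ± 5.74 FPKM in the controls to 167 ± 28.1 FPKM in the libraries labelled knockout (SD, n = 2 each; log2 fold change 2.70, SE 0.21). The glucose transporter gene Slc2a2 rose from 26.4 ± 3.88 to 134 ± 24.4 FPKM (2.29, SE 0.17), and Reg3a, which encodes an antimicrobial lectin, from 40.1 ± 7.16 to 181 ± 34.1 FPKM (2.15, SE 0.19). Adh4, an alcohol dehydrogenase gene, stood at 0.400 ± 0.278 FPKM in the controls and at 11.2 ± 3.00 FPKM in the libraries labelled knockout (3.11, SE 0.24). The other genes with the largest increases were Apobec2 at 2.90, Fam213a at 2.46, Acsm5 at 2.36, the noncoding BC064078 at 2.31, C87977 at 2.28 and Ano3 at 2.12. Among the genes that fell, Duox2, a hydrogen peroxide-forming oxidase gene, went from 163 ± 15.7 to 54.1 ± 5.95 FPKM (-1.57, SE 0.13), and Duoxa2, its maturation factor on the neighbouring stretch of chromosome 2 (122298900 to 122302885), from 132 ± 10.6 to 32.0 ± 7.35 FPKM (-2.03, SE 0.18). Mmp7, the metalloproteinase that activates Paneth cell defensins, fell from 166 ± 33.4 to 46.5 ± 1.28 FPKM (-1.80, SE 0.16), and Itln1, an intelectin gene, from 794 ± 134 to 284 ± 20.2 FPKM (-1.47, SE 0.16). The remaining genes with the largest decreases past the same threshold were Sh2d6 at -1.72, Khdrbs3 at -1.49, C2cd4b at -1.45, Mir1968 at -1.43, Sh2d7 at -1.39 and Ankrd37 at -1.29. Mir1968 lies within Grtp1 on the same strand and rested on 12 and 15 reads in the controls and on 3 in each library labelled knockout, Ankrd37 overlaps Ufsp2 on the opposite strand, and Cyp3a11, Reg3a and C87977 have close relatives, so reads of these genes could have been split or shared.

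The limma test called 94 of 12948 genes at an adjusted p under 0.05, of which 77 were higher and 17 lower in the libraries labelled knockout, and 23 were predicted genes or receptor segments. At an unadjusted p under 0.05 there were 970 higher and 2477 lower genes. The median log2 fold change of all genes tested was -0.15, median-ratio scaling moved it by 0.15, and medians of lists past the threshold are therefore also given relative to it. Of all genes tested 48.5% were lower and 14.9% higher in all 4 pairings of libraries, where chance gives 16.7% in each direction; after median-ratio scaling the shares were 28.3% and 27.9%. The share of higher genes among the calls was 81.9%, against 93.8% after median-ratio scaling (60 higher, 4 lower) and 92.4% after quantile normalization (61 higher, 5 lower). The calls lay close to the threshold: without a filter on low values 1 gene was called higher and 0 lower, and with the filter at a mean of 5 FPKM 2 and 0. Calls with a library left out are not counted here, because its group then keeps 1 library and the other group alone gives the spread. The authors' deposited table gave a q-value under 0.05 to 285 genes, 168 higher and 117 lower, and 25 of them were among the 94 genes called here. Both lists come from the same 4 libraries, so their overlap is no independent support.

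Genes of cholesterol synthesis had lower values in the libraries labelled knockout along most of the pathway. Hmgcs1, which makes HMG-CoA (chromosome 13, 119690351 to 119708260), stood at 139 ± 30.5 FPKM in the controls and 62.2 ± 17.2 FPKM in the libraries labelled knockout (log2 fold change -1.16, SE 0.26, limma adjusted p = 0.11), and the later enzyme genes Mvd, Fdft1 and Sqle gave -1.39, -1.34 and -1.18; Fdft1 overlaps Ctsb on the opposite strand, so its value is uncertain. All 21 measured genes of the list had negative log2 fold changes, with a median of -0.80, or -0.65 relative to all genes. With median-ratio scaling 18 were negative and 3 positive, and with quantile normalization 20 and 1. As scaled by the authors, 18 of the 21 were lower in all 4 pairings (85.7%, against 48.5% of all genes tested and 16.7% by chance). After median-ratio scaling 17 were (81.0%, against 28.3% of all genes tested). The late-step genes Ebp and Sc5d lay at -0.15 and -0.05, and median-ratio scaling put them at 0.0131 and 0.12. The list passed camera (adjusted p = 1.83e-05), and adjusted p = 0.969 with an estimated correlation, which was 0.81. By limma none of the 21 genes passed over all genes tested (0 also with voom, 17 at an unadjusted p under 0.05), and 16 passed when adjusted over the list alone. In the authors' deposited table Hmgcs1, Sqle and Fdps had q-values of 1.5e-05, 0.00131 and 0.029, the only list members under 0.05.

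**Figure D1:**
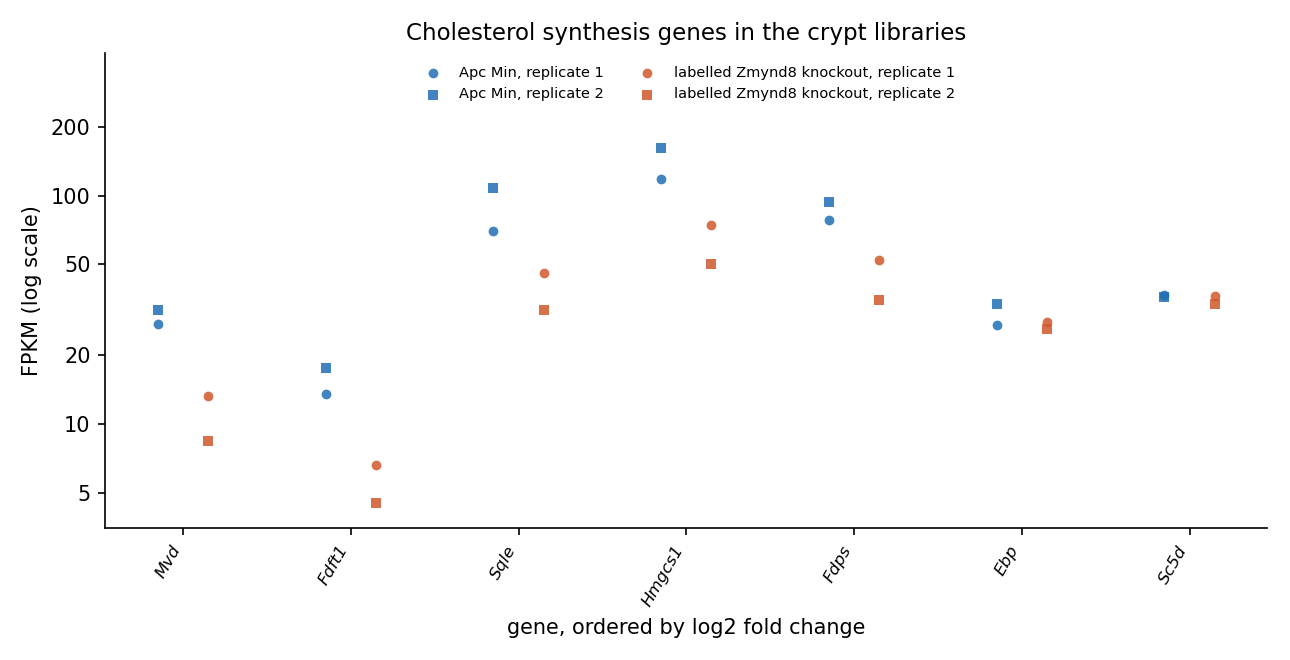
FPKM in each library, on a log axis, of the cholesterol synthesis genes named in the text, ordered by log2 fold change from the lowest; circles are replicate 1, squares replicate 2, blue the Apc Min controls and orange the libraries labelled Zmynd8 knockout. Both blue points of Mvd (27.3 and 31.5 FPKM) lie above both orange points (13.2 and 8.47 FPKM), while the points of Ebp and Sc5d overlap.

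The cholesterol list also differed within each group, as did other lists. Its mean log2 value was 4.86 and 5.19 in control replicates 1 and 2 and 4.42 and 4.07 in the libraries labelled knockout. The ileal and bile acid list had means of 7.77, 8.65, 8.05 and 6.88 in the same order, the proximal list 4.76, 4.27, 5.31 and 5.60, and the circadian list 3.03, 3.16, 3.57 and 3.53. The circadian list went the same way as the cholesterol list within each group and the opposite way between the groups. Between replicates of the same number, the median cholesterol fold change was -0.48 for number 1 and -1.15 for number 2.

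Most sterol uptake and sensing genes had negative values, though as a list they did not pass camera. Insig1 stood at 42.6 ± 1.65 FPKM in the controls and 23.3 ± 1.69 FPKM in the libraries labelled knockout (-0.84, SE 0.10, adjusted p = 0.051), and Srebf2, which encodes the transcription factor SREBP2, gave -0.70 (adjusted p = 0.090). Soat2, a cholesterol esterification gene, gave 0.83 (adjusted p = 0.075). Of 14 genes 12 were negative (8 after median-ratio scaling), around a median of -0.34, or -0.19 relative to all genes, and 8 were lower in all 4 pairings (57.1%, against 48.5% of all genes tested and 16.7% by chance). Camera gave adjusted p = 0.403, and fry adjusted p = 0.080, the smallest of the 40 lists; 1 gene higher and 3 lower passed adjusted over the list alone. Of 10 sterol efflux genes driven by LXR receptors, 5 had positive and 5 negative fold changes around a median of 0.00, or 0.15 relative to all genes (7 and 3 after median-ratio scaling, 6 and 4 after quantile normalization). Abca1 stood at 8.19 ± 4.65 and 17.8 ± 1.03 FPKM (1.13, adjusted p = 0.20) and Abcg5 gave 0.45. That list passed camera upwards (adjusted p = 0.0415), and adjusted p = 0.836 with an estimated correlation. Quantile normalization ended the call (adjusted p = 0.141), as did limma without the trend (0.0538). The 14 isoprenoid use genes did not pass (adjusted p = 0.777), with 12 negative here and 4 after median-ratio scaling.

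Acly, which makes cytosolic acetyl-CoA, fell from 34.5 ± 1.84 to 18.6 ± 0.690 FPKM (-0.86, SE 0.10, adjusted p = 0.045). The other fatty acid synthesis genes Fasn and Scd2 gave -0.99 (adjusted p = 0.057) and -2.20 (adjusted p = 0.074), with Scd2 at 126 ± 13.6 and 27.6 ± 10.8 FPKM. All 15 measured genes of this list had negative values, with a median of -0.53, or -0.38 relative to all genes, 1 passed over all genes tested and 6 adjusted over the list alone. As a list they passed camera downwards (adjusted p = 0.00268), and adjusted p = 0.8997 with an estimated correlation.

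Enterocyte genes were higher in the libraries labelled knockout and gave the largest list shift, with a median of 1.17, or 1.33 relative to all genes. Slc2a2, Mme and Treh rose, the peptidase gene Mme from 50.2 ± 1.44 to 147 ± 20.3 FPKM (1.52, SE 0.13) and the trehalase gene Treh from 51.9 ± 8.08 to 181 ± 27.2 FPKM (1.78, SE 0.17). Fabp1, the liver-type fatty acid binding protein gene, stood at 93.7 ± 47.9 and 858 ± 352 FPKM (3.22, SE 0.52, adjusted p = 0.095). Of 22 genes 21 were positive, 3 passed over all genes tested and 17 adjusted over the list alone. Camera gave adjusted p = 3.78e-20 upwards, and adjusted p = 0.819 with an estimated correlation.

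Markers of the proximal small intestine moved with the enterocyte genes. Adh6a stood at 47.0 ± 3.89 FPKM in the controls and 228 ± 78.3 FPKM in the libraries labelled knockout (2.21, adjusted p = 0.061), and Gata6, a transcription factor gene, gave 0.57 (adjusted p = 0.082). Of 9 proximal genes 8 were positive, around a median of 0.57, or 0.72 relative to all genes, with 0 past the limma threshold over all genes (1 with voom, 6 at an unadjusted p under 0.05) and 6 adjusted over the list alone. Camera gave adjusted p = 8.22e-06 upwards, and adjusted p = 0.819 with an estimated correlation. Fabp1 is among the genes that the proximal and enterocyte lists share. Ileal and bile acid genes did not pass (adjusted p = 0.891) and varied widely between pools. Fgf15, an ileal hormone gene, stood at 21.4 and 62.9 FPKM in the controls and at 20.3 and 3.89 FPKM in the libraries labelled knockout. Fabp6, the ileal bile acid binding protein gene, chosen after its values were seen, stood at 1459 and 7606 FPKM in the controls and at 2250 and 134 FPKM in the libraries labelled knockout.

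The glutathione genes Gstm3 and Gsta1 rose, Gstm3 from 14.5 ± 0.149 to 51.0 ± 9.34 FPKM (1.73, SE 0.15) and Gsta1 from 9.26 ± 0.710 to 21.7 ± 0.502 FPKM (1.15, SE 0.10). Of the 14 NRF2-linked genes in their list 7 were positive and 7 negative around a median of 0.07, or 0.22 relative to all genes (10 and 4 after median-ratio scaling, 9 and 5 after quantile normalization), and 6 passed higher and 3 lower adjusted over the list alone. Together they passed camera upwards (adjusted p = 0.00467), and adjusted p = 0.819 with an estimated correlation; quantile normalization ended the call (0.0692). Angptl4, a lipoprotein lipase inhibitor gene under PPAR control, rose from 9.16 ± 0.141 to 33.9 ± 1.61 FPKM (1.78, SE 0.09), and Creb3l3 gave 1.17 (adjusted p = 0.074). The 16 fatty acid oxidation and PPAR alpha genes were 9 positive and 7 negative around a median of 0.07, or 0.22 relative to all genes (10 and 6 after median-ratio scaling), with 5 higher and 1 lower adjusted over the list alone. That list passed camera upwards (adjusted p = 0.00469), and adjusted p = 0.969 with an estimated correlation; it was lost without control replicate 2 (0.261) and after quantile normalization (0.0692).

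Cell cycle genes were lower in the libraries labelled knockout in every member measured. Cdc20 stood at 23.3 ± 0.474 FPKM in the controls and 14.6 ± 0.726 FPKM in the libraries labelled knockout (-0.64, adjusted p = 0.067), Ccna2 gave -0.56 (adjusted p = 0.072) and the replication helicase gene Mcm5 -0.69 (adjusted p = 0.074). All 28 genes were lower in all 4 pairings (24 after median-ratio scaling, or 85.7% against 28.3% of all genes tested), with a median of -0.52, or -0.36 relative to all genes, and all stayed negative under both other scalings. By limma 0 passed over all genes tested (0 with voom, 24 at an unadjusted p under 0.05), and 23 passed adjusted over the list alone. The list passed camera (adjusted p = 1.30e-07), and adjusted p = 0.944 with an estimated correlation. Mean log2 values of the enterocyte list were 7.95 and 7.84 in the controls and 9.07 and 9.39 in the libraries labelled knockout. Fewer crypt cells in those pools and lower expression per cell therefore cannot be told apart.

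Stem cell and Wnt target genes were lower as lists, and their mean log2 values were highest in control replicate 1 (3.59 for Wnt targets and 3.96 for stem cell genes, against 2.37 and 3.33 in control replicate 2). The cyclin gene Ccnd1 fell from 33.3 ± 1.38 to 16.2 ± 1.40 FPKM (-0.99, SE 0.10, adjusted p = 0.044). Axin2, a feedback target of Wnt signalling, gave -0.81 (adjusted p = 0.091), and the stem cell gene Lgr5 stood at 14.8 and 3.48 FPKM in the controls and at 2.74 and 3.19 FPKM in the libraries labelled knockout. The 18 Wnt targets had a median of -0.80, or -0.65 relative to all genes, with 17 negative, 1 past the threshold over all genes and 2 adjusted over the list alone. They passed camera (adjusted p = 0.0137), with adjusted p = 0.969 with an estimated correlation, and did not pass without control replicate 1 (0.276, with 14 of the 18 genes still tested) or at the filter of 5 FPKM (0.0939, with 11). The 15 stem cell genes, some of which (Lgr5 and Axin2 among them) are Wnt targets too, were all negative with a median of -0.58, or -0.42 relative to all genes, with 0 past limma's threshold over all genes (0 with voom, 7 at an unadjusted p under 0.05) and 4 adjusted over the list alone. They passed camera (adjusted p = 0.0129), with adjusted p = 0.969 with an estimated correlation, and did not pass without control replicate 1 (0.0677, with 13 of the 15 genes still tested).

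YAP targets did not pass camera as a list, which does not show that they were unchanged. Ccn1, listed as Cyr61, stood at 4.55 ± 2.15 FPKM in the controls and 3.54 ± 0.344 FPKM in the libraries labelled knockout (-0.24, 95% interval -1.03 to 0.55, adjusted p = 0.63), and Ccn2, listed as Ctgf, at 2.23 ± 0.905 and 1.84 ± 0.272 FPKM (-0.16, 95% interval -0.76 to 0.44, adjusted p = 0.67). Ankrd1 was not analysed here. Of 18 targets 7 were positive and 11 negative, and under both other scalings 11 were positive and 7 negative. The median of -0.04 and the camera direction, which was upwards relative to all genes (adjusted p = 0.393), differed in sign. Genes of fetal-type or regenerating epithelium did not pass either (median -0.84, or -0.69 relative to all genes, adjusted p = 0.234), except downwards in 3 of 12 other settings, and neither did 7 Notch pathway genes (adjusted p = 0.956).

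Among secretory cell markers, the Paneth and tuft lists were lower. Besides Mmp7 and Itln1, which fell, the Paneth genes Ang4 and Defa17 stood at 392 ± 17.7 and 250 ± 27.1 FPKM in the controls and at 202 ± 16.6 and 111 ± 15.3 FPKM in the libraries labelled knockout (-0.96 and -1.17, adjusted p = 0.057 for both); the defensins are near-identical copies whose reads could be shared. Of 19 Paneth genes 17 were negative, around a median of -0.87, or -0.71 relative to all genes, 2 passed over all genes tested, and 8 lower and 1 higher adjusted over the list alone. The list passed camera (adjusted p = 0.0211), with adjusted p = 0.969 with an estimated correlation, and was lost without control replicate 2 (0.276, with 18 of the 19 genes still tested) or without replicate 1 of the libraries labelled knockout (0.319). Of 10 tuft cell genes 8 were negative, around a median of -0.95, or -0.80 relative to all genes, 1 (Sh2d6) passed over all genes and 5 adjusted over the list alone; Rgs13 stood at 2.04 ± 0.0195 and 0.227 ± 0.230 FPKM (-1.32, adjusted p = 0.061). The tuft list passed camera (adjusted p = 0.0357), with adjusted p = 0.864 with an estimated correlation, and did not pass without either control library (0.468 without replicate 1, 0.680 without replicate 2), where the filter on low values left 6 of the 10 genes. Goblet and enteroendocrine markers did not pass (adjusted p = 0.466 for both), except in 1 other setting each.

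Most genes of the circadian list, fixed as one of the technical lists, were higher in the libraries labelled knockout. Dbp rose from 15.1 ± 0.0653 to 28.2 ± 2.05 FPKM (0.86, SE 0.10, adjusted p = 0.046), and Per1 stood at 4.98 ± 0.357 and 9.74 ± 0.480 FPKM (0.85, adjusted p = 0.057). Of 13 circadian genes 12 were positive, around a median of 0.45, or 0.60 relative to all genes, 1 passed over all genes tested and 9 adjusted over the list alone. Camera gave adjusted p = 9.47e-08 upwards, and adjusted p = 0.819 with an estimated correlation.

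Interferon response genes were higher in the libraries labelled knockout, with a median of 0.34, or 0.49 relative to all genes. Usp18 stood at 10.1 ± 0.192 and 19.0 ± 2.44 FPKM (0.85, adjusted p = 0.064) and Ifit3 at 6.60 ± 0.718 and 10.1 ± 0.430 FPKM (0.54, adjusted p = 0.096). Of 29 genes 21 were positive, with 0 past limma's threshold over all genes (0 with voom; unadjusted, 13 higher and 1 lower) and 1 adjusted over the list alone. As a list they passed camera upwards (adjusted p = 1.30e-07), and adjusted p = 0.819 with an estimated correlation. MHC class I genes went both ways, with H2-Q1 at 1.28 (adjusted p = 0.059) and Tapbp at -0.61 (adjusted p = 0.076), and missed the threshold as a list (adjusted p = 0.0629). That result depended on the setting: the list passed upwards in 6 of 12 others, with adjusted p = 9.7e-04 without control replicate 2, and pointed downwards without control replicate 1 (0.968). MHC class II genes did not pass (adjusted p = 0.901).

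Single stress and defence genes changed within lists that did not pass. Herpud1, an endoplasmic reticulum stress gene, rose from 51.5 ± 2.02 to 105 ± 1.25 FPKM (1.01, SE 0.10, adjusted p = 0.042; list 0.827). The hypoxia genes Ankrd37 and Adm fell, Adm from 3.65 ± 0.224 to 1.05 ± 0.00991 FPKM (-1.18, SE 0.13), while the hexokinase gene Hk2 gave -1.68 (adjusted p = 0.062; list 0.176, past the threshold in 3 of 12 other settings). In the antimicrobial list Reg3a rose while Duox2 and Duoxa2 fell (list 0.790). The p53 target Pmaip1 gave 0.71 (adjusted p = 0.059; list 0.854). In this paragraph the list values are camera adjusted p-values.

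Markers of other cell types showed no list shift past the camera threshold. The adjusted p-values were 0.554 for T cells and intraepithelial lymphocytes, 0.554 for B and plasma cells, 0.895 for myeloid cells, 0.978 for stroma, 0.901 for pancreas acinar cells and 0.827 for erythroid cells. Apart from the circadian list, which was fixed as a technical list and passed as given above, and the sex-linked list, the technical lists did not pass. They gave 0.123 for mitochondrially encoded genes, 0.288 for ribosomal protein genes, 0.554 for replication histones and 0.466 for genes induced by tissue handling. The list of known ZMYND8 partners gave 0.466. Of the lists in this paragraph, those of T cells, B and plasma cells, mitochondrially encoded genes and ribosomal protein genes passed in the same direction in 1 to 3 other settings each, and the erythroid list passed upwards without control replicate 2 (0.00315) and downwards without control replicate 1 (0.00987). The sex-linked list (0.713) holds Xist and Y-linked genes, which go opposite ways when the mix of sexes differs, so its test does not bear on that mix. Of 40 lists 14 passed camera at the preset correlation, and none of the 14 held with an estimated correlation, where the smallest adjusted p was 0.819, or with fry. That correlation is estimated on 2 residual degrees of freedom, so these misses do not show that the lists are unchanged.

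**Figure D2:**
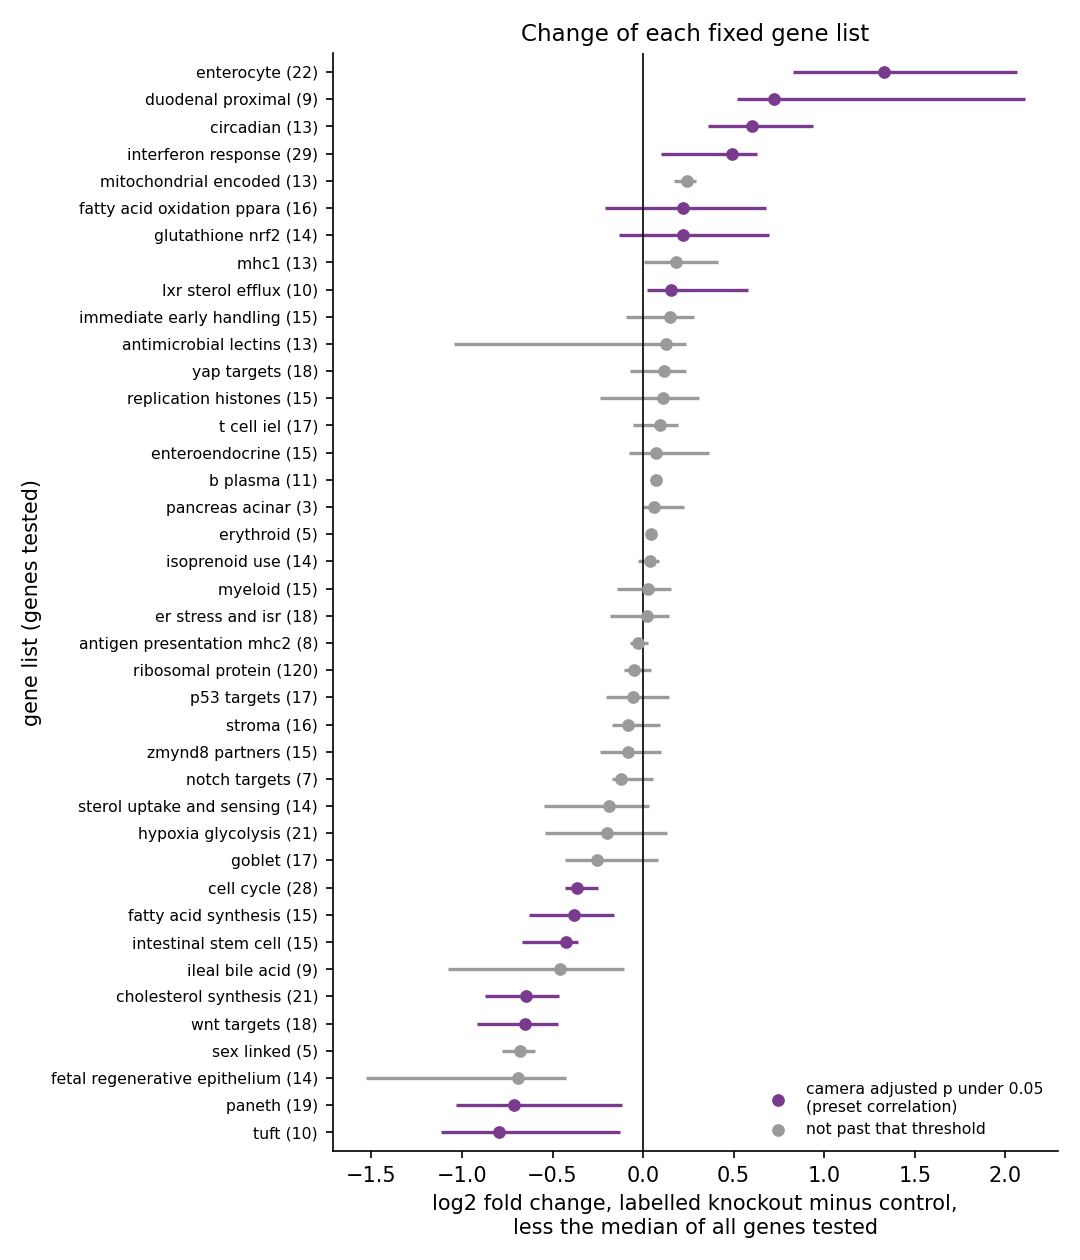
Median log2 fold change of the members of each of 40 gene lists, labelled knockout minus control, less the median of all genes tested, with the number of genes tested in brackets; points are medians, lines the interquartile ranges, and purple marks the 14 lists past a camera adjusted p of 0.05 at the preset correlation. The enterocyte list lies farthest to the right at 1.33 and the tuft list farthest to the left at -0.80, while none of the 14 passed with an estimated correlation.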

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

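The voom fit on recovered reads was chosen after the results were seen, and all other settings before. The number of genes higher in the libraries labelled knockout, 77, was 41 without the trend, 1 without the filter on low values, 2 at the filter of 5 FPKM, 123 with voom, and 0 to 230 with libraries left out. The number lower, 17, was 9 without the trend, 5 after quantile normalization, 4 after median-ratio scaling, 0 under either change of filter, 27 with voom, and 0 to 386 with libraries left out. With the replicate number as a block, 0 genes were called in either direction (907 higher and 2245 lower at an unadjusted p under 0.05), and the sterol efflux list had an adjusted p of 0.0525; nothing in the labels pairs libraries of the same number, across genes their deviations had Pearson's r = 0.045, a few small RNA genes such as Rn7s1 did split by number in both groups, and the block uses up 1 residual degree of freedom. The adjusted p of the cholesterol synthesis list was 0.969 with an estimated correlation and 0.261 with fry, both of which passed 0 of 40 lists. In the other 12 settings it ran from 3.65e-08 to 0.00873. The other 2 ways of splitting the 4 libraries in pairs called 1 and 0 genes against 94, and these splits are too few for a share under 0.05. Zmynd8 lay between 0.09 and 0.56 with libraries left out. Signs of a few genes near 0 reversed. Ebp was 0.0131 after median-ratio scaling. Sc5d was 0.0118 after quantile normalization, 0.12 after median-ratio scaling, and -0.11 to 0.0077 with libraries left out. Cyr61 ran from -0.64 to 0.17 and Ctgf from -0.45 to 0.13 with libraries left out, positive without control replicate 1. Of 32 named genes past the threshold, 32 were not past it without the filter on low values, and 20 of 21 still tested at the filter of 5 FPKM. Such losses numbered 12 after median-ratio scaling, 11 after quantile normalization, 11 without the trend, and 2 each with voom and the other pseudocount. Median-ratio scaling moves all genes of a library alike by construction; the cause of the other differences was not tested.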

Other observations

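The gene families, every gene named here outside the naming rule and every test below were chosen after the results had been seen. P-values of the families therefore describe genes already seen and are no independent test. Some genes of the Hox family, which set position along the gut, had lower values in the libraries labelled knockout. All 9 measured were negative (8 of 9 under both other scalings), with a median of -1.20. The genes Hoxb5 to Hoxb9 ran from -1.20 to -2.54, while Hoxb4, Hoxc8, Hoxb2 and Hoxa5 gave -0.51, -0.44, -0.15 and -0.02. Hoxb5 fell from 4.06 and 3.80 FPKM in the controls to 1.08 and 1.21 FPKM in the libraries labelled knockout (-1.20, SE 0.13, adjusted p = 0.045), though it overlaps Hoxb5os on the opposite strand and is uncertain, and Hoxb9 stood at 11.5 and 7.03 FPKM against 1.88 and 0.0231 FPKM (-2.54, adjusted p = 0.13). The family had a camera adjusted p of 0.00689 over the 8 families tested, and adjusted p = 0.246 with an estimated correlation.

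Genes of drug and steroid metabolism lay higher in the libraries labelled knockout. In the Cyp3a family all 4 genes were positive, among them Cyp3a11 and Cyp3a13, which rose, the latter from 159 ± 7.04 to 358 ± 41.9 FPKM (1.16, SE 0.13, adjusted p = 0.046); Cyp3a25 gave 1.78 (adjusted p = 0.053). Of 7 Ugt genes, which encode glucuronosyltransferases, 6 were positive, and Ugt2a3 stood at 8.99 ± 5.27 and 52.8 ± 9.72 FPKM (2.53, adjusted p = 0.10). The camera adjusted p was 5.05e-07 for Cyp3a and 6.60e-06 for Ugt, and adjusted p = 0.107 with an estimated correlation for both. Of 5 Cyp2c genes 4 were positive (1.82e-05, and 0.214 with an estimated correlation), and of 20 Gst genes 13 (2.01e-05, and 0.246). Immunoglobulin variable segments (174 genes) had 108 positive values and 3 that rose (2.32e-07, and 0.0942). Of 229 Slc transporter genes 102 were positive and 127 negative around a median of -0.07 (133 and 96 after median-ratio scaling, 130 and 99 after quantile normalization), while camera pointed upwards (3.02e-04, and 0.176). The 8 keratin genes did not pass (0.987). Members of the enzyme families are similar in sequence, so reads of some could have been shared; for comparison, Cyp3a11 and Cyp3a13 gave 2.70 and 1.16.

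The lower cholesterol synthesis genes were set against where and when tissue was taken and against the sex of the mice, with genotype itself left untested because it runs with the groups. With a proximal-minus-ileal score as a covariate the list median relative to all genes went from -0.65 to -0.22, and with the proximal score alone to 0.21; it went to 0.04 with Gata4 alone, -0.42 with the ileal score alone and -0.41 with Fabp6 alone, each on 1 residual degree of freedom. More villus and fewer crypt cells would lower crypt genes alike: the cholesterol mean less the cell cycle mean was 1.09 and 1.59 in the controls and 1.22 and 0.89 in the libraries labelled knockout, a difference of -0.28 with overlapping groups. The mean log2 value of the circadian list was at least 0.37 higher in each library labelled knockout than in each control. A difference in time of day or feeding, if there was one, would therefore also run with the labels. The mean of Y-linked genes was 2.04 and 2.94 in the controls and 2.02 and 1.16 in the libraries labelled knockout. With it as a covariate the cholesterol list median relative to all genes went to -0.31. These explanations and genotype cannot be told apart, because region, clock and villus genes differ between the groups and 4 libraries leave 1 residual degree of freedom for any covariate.

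Control replicate 1 held more RNA of Wnt target and of fetal or regenerative epithelium genes than control replicate 2, such as Wif1 (33.2 and 1.25 FPKM), Nkd1 (26.6 and 3.23 FPKM) and Clu (330 and 20.8 FPKM). The 18 Wnt targets had a median difference of 0.92 relative to all genes, with 17 higher in replicate 1, and the 14 fetal or regenerative genes 1.48, with 13 higher; as these are the observation itself, adenoma tissue in that pool stays open and without a test of its own. The lists argue against more of all non-epithelial cells alike, though each pool is 1 library. The T cell list lay at -0.36 (4 of 17 genes higher) and the myeloid list at -0.16, while stroma lay at 0.29 (12 of 16) and B and plasma cells at 0.50 (6 of 11). More of some of these types alone stays open, with Mcpt1, a mast cell gene, at 118 and 12.6 FPKM. The labels name no biological difference between these pools, so none from the design was tested. The female-expressed Xist stood at 22.6 and 0.0183 FPKM in control replicates 1 and 2. The ileal and bile acid list lay at -0.94 relative to all genes, with 1 of 9 genes higher in replicate 1. Sex of the mice and gut region were not tested for this pattern and stay open.

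Zmynd8 was not lower in the libraries labelled knockout, with a log2 fold change of 0.33 at gene level. RNA of non-epithelial cells could make up for a loss in the epithelium. The 4 non-epithelial lists showed no rise as large as that of Zmynd8, with a highest median of -0.0606 and all 4 upper quartiles at most 0.04. Relative to all genes their medians lay at 0.09 for T cells, 0.07 for B and plasma cells, 0.03 for myeloid cells and -0.08 for stroma. More Zmynd8 RNA per non-epithelial cell, and cell types without a list, could not be tested and stay open. A deletion of part of the gene that leaves transcripts in place, and exchanged or wrong group labels, cannot be told apart: the 0.33 is a value over all exons, and the lowest library labelled knockout lay 0.0646 above the highest control. Exon-level reads would decide and were not used here.

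A few small noncoding RNA genes differed by replicate number in both groups. Of 10 genes of any kind over 4-fold apart in both groups, 7 were apart the same way by replicate number and 3 the other way. Some of the 7 are immunoglobulin genes. Scarna9 did not split this way, at 2.13 and 16.1 FPKM in the controls and 3.07 and 3.97 FPKM in the libraries labelled knockout. Rn7s1 stood at 389 FPKM in control replicate 1, 6.10 FPKM in control replicate 2, and 328 and 2.65 FPKM in the libraries labelled knockout, Rn7sk at 105, 5.13, 149 and 3.83 FPKM, and Rnu1a1 at 17.5, 0, 46.4 and 0.254 FPKM. Xist, expressed in females, stood at 22.6 and 0.0183 FPKM in the controls and 24.3 and 25.2 FPKM in the libraries labelled knockout, and the Y-linked Ddx3y at 5.18 and 9.30 against 4.37 and 1.63 FPKM.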
